A study of Mus musculus with 9 samples.

How the data were processed

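Bulk RNA sequencing was done on mouse tissue recovered after blastoids had been placed in the uterus of pseudopregnant mice. Per the labels, total RNA was isolated with TRIzol, libraries were made with Smart-Seq2 chemistry and the Nextera XT kit, and paired reads of 150 bp were read on a HiSeq X instrument. The submitters' processing notes name HISAT2, StringTie and the mm10 genome, without versions or the step each was used for. The deposited table gives FPKM (fragments scaled to transcript length and to the number of mapped fragments) for 31090 genes in 9 libraries, as the authors computed it. No gene was 0 in every library, and 177 entries had no symbol.

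The table carries Ensembl identifiers, and 30638 of them were found in GENCODE release M21 on GRCm38, of which 606 had the same position there and 29498 the same symbol. The positions in the table therefore come from another build or annotation for most genes. Coordinates given here are those of GENCODE M21 on GRCm38, looked up by identifier, and the positions in the table were not used.

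The depth was read from the low values. In each library FPKM times exon length fell on whole multiples of a single step, which was estimated from genes with 1 annotated exon longer than 1 kb, with 89.8% to 94.5% of the values under 15 fragments within 0.05 of a whole number. The steps imply 15375000 to 19113000 fragments per library. At that depth 3 fragments on a transcript of 1 kb correspond to 0.157 to 0.195 FPKM, so that values below this level were treated as near the floor. These limits cover counting error only, because the fragments carry no molecular identifiers. Replicate pairs were compared by the mean chi-square of the implied fragments per gene, for which sampling noise alone gives 1. It was 2.81 to 15.2 in ctrl DEC, 30.6 to 86.6 in ctrl EMB and 4.25 to 8.16 in H2O2 DEC, and no pair was identical, so no library was a copy of another. Noise from library preparation also raises this value, so it cannot tell biological replicates from repeated libraries of 1 RNA sample. Each library was counted as 1 sample because the labels give biological replicates.

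FPKM values are not counts, so no count model was used for the main results. Values were transformed as log2(FPKM + 1), and the 13386 genes with a mean of at least 1 FPKM over all 9 libraries were tested. Fold changes on this scale understate the change of genes with low values. A model with 1 mean per group was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3, with an eBayes trend on expression, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. The comparisons were H2O2 DEC against ctrl DEC and ctrl EMB against ctrl DEC. H2O2 DEC and ctrl EMB were not compared with each other because both tissue and treatment differ between them.

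Gene lists, 27 in number and holding 689 genes of which 662 were listed in the table, were fixed before the data were examined. Lists with at least 5 measured members were tested with camera from limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over lists, and 4 lists had too few measured members. The same test with an estimated correlation, and fry, were run beside it. Counts of members are given over all genes tested and, where they differ, adjusted over the list alone. Another 12 marker lists were written after the values of the fixed lists had been seen: ovarian somatic cells, oocyte, oviduct ciliated cells, adrenal cortex, adipose, liver, kidney, skeletal muscle, uterine position, post-implantation embryo, placental lactogens with embryonic growth genes, and Y-linked genes. All 6 genes of the placental and growth list, the liver gene Ttr and the muscle gene Ckm were also on fixed lists, so their values were known by then.

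The genes named were chosen by a rule fixed before the data were examined. It took, per comparison, the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap and whose higher group had a mean of at least 5 FPKM, leaving predicted genes as a count. It also took up to 3 called members per gene list that passed its test or had at least 3 called members, or the 2 members with the highest mean where none was called. The anchors were Prl8a2, Bmp2, Hand2, Prl3d1, Tpbpa, Afp, Pou5f1, Hbb-bh1, Prf1, Mki67, Cdkn1a and Hmox1. Hbb-bh1 was not listed in the table. Other genes named were chosen after their values were seen, to identify the members behind a list's count or to give levels in the added marker lists.

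The alternatives tried were other pseudocounts, no filter and a filter at a mean of 5 FPKM, rescaling every library to the same total, quantile normalization, median centring, leaving out globin and mitochondrial-encoded genes, a fit to only the 6 samples compared, array weights, robust and untrended eBayes, the replicate number as a block, and leaving out each library in turn. After the data had been seen, voom on the implied fragments and removal of each library's trend with transcript length and GC content were added. The overlap of the comparisons, which share the ctrl DEC libraries, was set against 100 simulated pairs of unchanged groups. The pipeline was tested on simulated data with 100 changed genes per size: in the H2O2 DEC design 28% of changes of 0.5 and 90% of changes of 1 on the log2 scale were recovered, and in the ctrl EMB design 37% and 83%, with 7 false calls among 13158 unchanged genes. A cell cycle list shifted by 0.5 was called in both designs and 0 of the other lists were. The simulated libraries had the same spread per gene in every group, whereas the real ctrl EMB replicates spread more than the others. The rates given for the ctrl EMB design may therefore not hold in the real comparison. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and statmod 1.5.0 was used with limma.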

Results

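The data set held 9 mouse RNA-seq libraries in 3 groups of 3 biological replicates. Blastoids are structures grown from cultured cells that resemble an early embryo, and the decidua is the stroma of the uterus as it transforms around an implanting embryo. The ctrl DEC group was decidua formed after transfer of control TBL-blastoids (the labels do not expand TBL), the ctrl EMB group was the embryonic-like tissue found in such deciduas, and the H2O2 DEC group is given in the labels as decidua formed after transfer of blastoids named for H2O2, an oxidant. The columns of the deposited table and the sample descriptions call this group old DEC, and the series description equates old with the H2O2 blastoids, so every H2O2 DEC value rests on that statement and on the sample titles. Blastoids were transferred to pseudopregnant mice at 2.5 days post coitum. The series description places collection 6 days later and the extraction protocol at day 3, so the stage is uncertain. The labels do not say whether each replicate came from its own mouse, so p-values measure the spread between these samples.

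Each library held a total of 328125 to 376404 FPKM, from an implied 15375000 to 19113000 fragments, and 12525 to 13688 genes at 1 FPKM or more. Mitochondrial-encoded genes took 8.99% to 13.4% of the total in ctrl DEC, 6.43% to 15.6% in ctrl EMB and 10.5% to 11.9% in H2O2 DEC. Pearson's r of log2(FPKM + 1) across genes, which are not independent replicates, was 0.988 to 0.995 within ctrl DEC, 0.952 to 0.980 within ctrl EMB and 0.988 to 0.990 within H2O2 DEC. Between ctrl DEC and ctrl EMB it was 0.961 to 0.980, and between ctrl DEC and H2O2 DEC 0.758 to 0.765. The first principal component held 85.3% of the variance and set the 3 H2O2 DEC libraries apart from the other 6. The second held 5.69% and spread the ctrl EMB libraries.

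**Figure D1:**
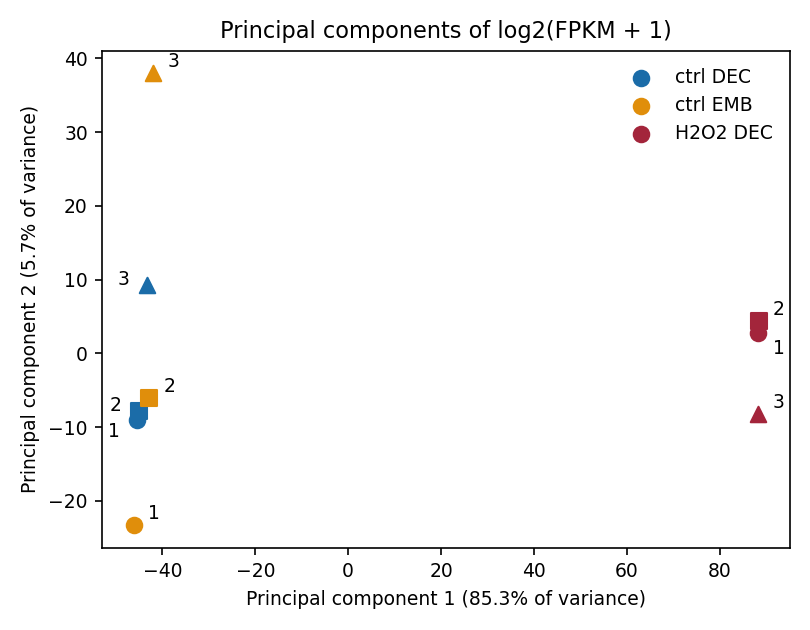
Scores of the 9 libraries on the first principal component (horizontal, 85.3% of the variance) and the second (vertical, 5.69%) of log2(FPKM + 1), in arbitrary units. Colours give the group and symbols and digits the replicate; the H2O2 DEC libraries lie on the right, and ctrl DEC and ctrl EMB lie together on the left.

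The first comparison asked how the samples labelled as decidua from H2O2 blastoids differed from decidua from control blastoids. All 3 H2O2 DEC libraries also held transcripts typical of the ovary, as given below, so the changes cannot be read as changes within decidua. Genes of the decidual response were far lower in H2O2 DEC. Prl8a2, a prolactin-family hormone made by decidual cells, fell 62.4-fold, from 6129 ± 267 FPKM in ctrl DEC to 98.1 ± 9.93 FPKM in H2O2 DEC (SD, n = 3 in each group here and below; log2 change -5.95, SE 0.16, adjusted p = 4.47e-09). Prl3c1, another decidual prolactin, fell from 798 ± 59.6 to 0.230 ± 0.0376 FPKM. Among the largest rises were Akr1c18, which inactivates progesterone, at 7990.2 ± 500.0 FPKM against 0.548 ± 0.311 FPKM (log2 change 12.35, SE 0.26, adjusted p = 9.28e-10), and Star, which brings cholesterol into mitochondria, at 568 ± 22.4 FPKM against 3.57 ± 0.159 FPKM.

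Other genes with the largest rises were Hsd3b1, an enzyme of steroid synthesis, at 1894 ± 11.4 FPKM against 0.0102 FPKM, and Inha, the alpha subunit of inhibin, at 1015 ± 45.9 FPKM against 2.08 ± 0.341 FPKM. Cyp17a1, an enzyme of androgen synthesis, reached 250.1 ± 3.21 FPKM and was listed at 0 in each ctrl DEC library. Ptgfr, the receptor of prostaglandin F2 alpha, stood at 252 ± 12.4 FPKM against 0.134 ± 0.0392 FPKM. Akr1cl and Cyp4f18 reached 451 ± 15.8 and 187 ± 0.937 FPKM, against 0.00447 and 0.143 FPKM. The largest falls after Prl3c1 were those of Krtdap, a protein of differentiating keratinocytes, and of the prolactin-family gene Prl6a1, at log2 changes of -7.02 and -6.78. Sfrp5, a secreted Wnt antagonist, fell from 504 ± 33.7 to 3.98 ± 0.328 FPKM. The hormone genes Sct (secretin) and Pyy (peptide YY), the metallothionein Mt4 and the prolactin-family gene Prl8a9 fell, with log2 changes of -6.61, -6.29, -6.47 and -6.33. The highest adjusted p of these 16 genes was 1.17e-06, for Mt4. Hsd3b1 belongs to a family of similar copies whose reads may be split between them, so its level is uncertain.

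On GRCm38, Akr1c18 (ENSMUSG00000021214) lies on chromosome 13 from 4132615 to 4150654 and Prl3c1 (ENSMUSG00000017922) on the same chromosome from 27196659 to 27203749, within the cluster of prolactin-family genes that also holds Prl6a1 (27312627 to 27319252) and Prl8a9 (27557995 to 27564606). Cyp17a1 (ENSMUSG00000003555) lies on chromosome 19 from 46667165 to 46673172, Star (ENSMUSG00000031574) on chromosome 8 from 25806555 to 25815982, and Sfrp5 (ENSMUSG00000018822) on chromosome 19 from 42197971 to 42202252. All of these are annotated as protein-coding genes, and each value sums over the gene's exons.

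**Figure D2:**
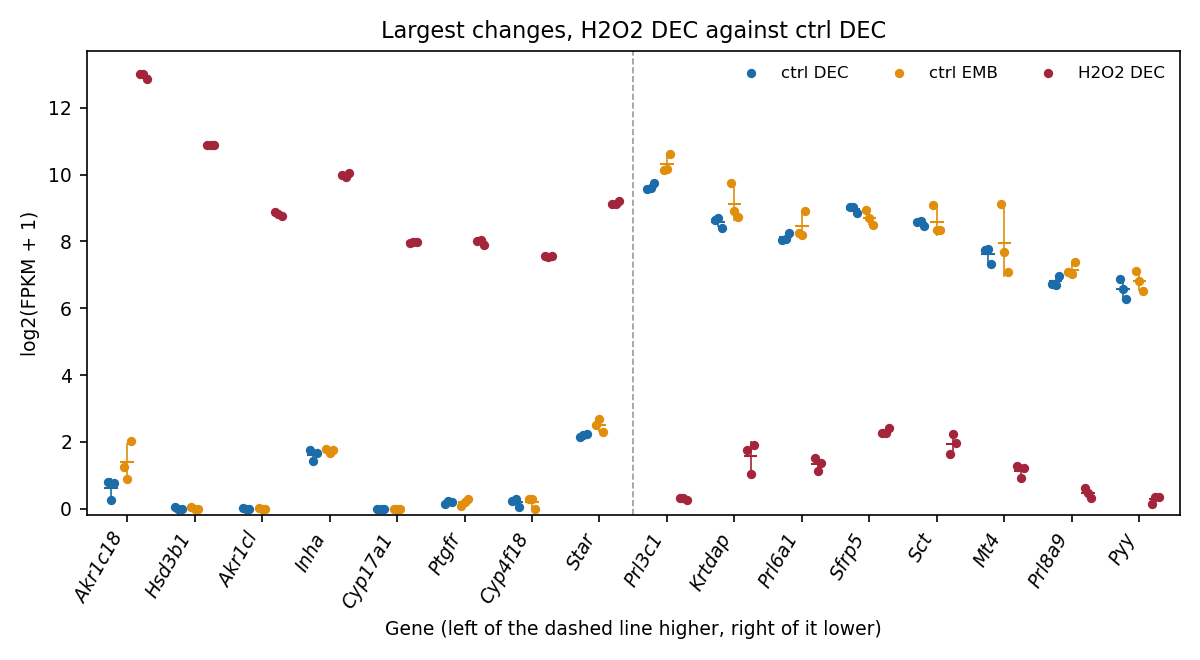
Log2(FPKM + 1) of each library (points) for the 8 genes with the largest rises and the 8 with the largest falls in H2O2 DEC against ctrl DEC, with group means (horizontal bars) and SD (vertical bars, n = 3). The ctrl EMB libraries lie near ctrl DEC for these genes and far from H2O2 DEC; Akr1c18 has a log2 change of 12.35 and Prl3c1 of -9.34.

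In all, 4933 genes were higher and 3124 lower in H2O2 DEC among the 13386 tested, which is 60.2% of them. More than 2-fold changes numbered 1857 higher and 1283 lower, and 301 of the higher and 255 of the lower genes were predicted genes. The values of the groups did not overlap for 9824 genes, or 73.4%, where chance gives 10%. With quantile normalization the split was 3897 higher and 4062 lower and with median centring 3568 and 4463, settings that moved the median log2 change of all genes by -0.15 and -0.21 (the main median was 0.12), while rescaling every library to the same total gave 5361 and 2769. No gene called here was called in the opposite direction under any alternative, and a filter at a mean of 5 FPKM, which left 8044 genes, gave 2598 higher and 2207 lower.

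Of the 30 measured genes of the decidualization list, 23 fell, 5 rose and 2 did not pass the test (median log2 change -2.0, camera adjusted p = 7.90e-08, and adjusted p = 0.00678 with an estimated correlation). Hand2, a transcription factor of the uterine stroma, fell from 508 ± 52.0 to 12.1 ± 0.499 FPKM, and Bmp2, a growth factor required for decidualization, from 335 ± 10.7 to 7.86 ± 0.593 FPKM. The stromal homeobox genes Hoxa10 and Hoxa11 fell by 4.15 and 4.05 on the log2 scale. The 5 that rose were Cyp11a1, the first enzyme of steroid synthesis, Foxo1, Fkbp5, Htra1 and Ptgs2, with log2 changes of 3.45, 2.93, 2.09, 1.35 and 0.97. Of the 5 measured genes of the trophoblast list, 4 fell and 1 rose (median -2.56, adjusted p = 0.0174), a call not kept at adjusted p = 0.127 with an estimated correlation. The fallers Gjb3, Tfap2c, Gata3 and Prl7b1 were all present in ctrl DEC, Gjb3 at 27.1 ± 4.41 FPKM, Tfap2c at 12.8 ± 0.973 FPKM and Gata3 at 14.3 ± 0.562 FPKM. Peg10, an imprinted gene, rose by 1.92. The trophoblast genes Prl3d1 and Tpbpa were too low to test, at 0.0436 and 0.577 FPKM in ctrl DEC.

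Genes of the cell cycle were lower together, with 26 of 28 measured members falling, 0 rising and 2 not past the test (median -0.99, adjusted p = 9.56e-12, and adjusted p = 0.00414 with an estimated correlation), or 27 falling adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, fell 27.0-fold from 1028 ± 8.98 to 38.1 ± 3.73 FPKM. Ccne1 (cyclin E1) and the mitotic kinase Plk1 fell by 2.16 and 1.78 on the log2 scale, and the proliferation marker Mki67 from 26.3 ± 1.90 to 14.5 ± 0.360 FPKM. The endothelial list had 14 of 21 members lower and 2 higher (median -0.46, adjusted p = 0.000594, but adjusted p = 0.127 with an estimated correlation). Plvap, a protein of fenestrated endothelium, fell from 111 ± 10.7 to 24.0 ± 1.75 FPKM, Notch4 by 1.86 and the lymphatic marker Lyve1 by 1.85. Nuclear genes of oxidative phosphorylation had 13 of 27 lower and 1 higher (median -0.41, adjusted p = 0.00513, but adjusted p = 0.641 with an estimated correlation), or 12 lower adjusted over the list alone, and the list was not called with quantile normalization. Cox5a, a subunit of cytochrome oxidase, fell from 83.7 ± 6.94 to 26.4 ± 2.19 FPKM, while Atp5o and Cycs fell by 0.91 and 0.90. The call of Atp5o ended without ctrl DEC replicate 1 (adjusted p = 0.0961) or 2 (0.0937) or H2O2 DEC replicate 1 (0.0747), 2 (0.1) or 3 (0.0677), in a range over alternatives of 3.67e-05 to 0.1. Ribosomal protein genes had 20 of 79 lower and 4 higher (median -0.19, adjusted p = 0.0197, but adjusted p = 0.822 with an estimated correlation), or 12 and 3 adjusted over the list alone, and the list was not called with the filter at 5 FPKM or with quantile normalization. Its largest changes, Rpl26 (-2.64), Rpl35a (1.76) and Rpsa (-1.51), are of genes with processed copies that can share reads, so they are uncertain.

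The uterine epithelium and gland list had 13 of 17 measured members higher, 3 lower and 1 not past the test (median 1.51, adjusted p = 0.00919, but adjusted p = 0.289 with an estimated correlation). Sprr2f, a cornified-envelope protein of the uterine epithelium, rose 18.8-fold to 155 ± 13.9 FPKM, the epithelial transcription factor Elf3 24.9-fold to 41.3 ± 1.25 FPKM and the tight-junction gene Cldn7 14.4-fold to 24.7 ± 1.0 FPKM. The smooth muscle list had 11 of 17 higher and 1 lower (median 1.09, adjusted p = 0.0208, but adjusted p = 0.127 with an estimated correlation), with Cnn1 (calponin) at 91.7 ± 6.24 against 22.1 ± 1.44 FPKM, Synm at 14.9 ± 1.83 against 3.23 ± 0.10 FPKM and the myosin gene Myh11 at 54.1 ± 5.53 against 14.2 ± 1.48 FPKM. The extraembryonic endoderm list had 8 of 13 higher and 2 lower (median 1.10, adjusted p = 0.0268, but adjusted p = 0.135 with an estimated correlation). It was not called without a filter, with the filter at 5 FPKM or with voom on the implied fragments. The members that moved most were Gata4 and Apoa4, at 35.6 ± 2.62 and 11.1 ± 1.73 FPKM and listed at 0 in each ctrl DEC library, and Apoa1, at 20.1 ± 1.94 against 0.0767 FPKM. Gata4 is also a transcription factor of ovarian somatic cells, and Apoa1 and Apoa4 are apolipoproteins of liver and gut. Afp, the main secreted protein of the yolk sac, was near 0 in both groups, at 0.0118 and 0.0280 FPKM.

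The 3 H2O2 DEC libraries also held transcripts typical of the ovary. Of 20 tested markers of ovarian somatic cells 19 were higher than in ctrl DEC, and of 17 tested oocyte markers 17 were higher, from lists written after the data were first seen. The oocyte genes Zp3, a protein of the egg coat, and Gdf9, an oocyte growth factor, stood at 34.4 ± 1.82 and 34.2 ± 4.31 FPKM, against 0.0287 and 0.178 FPKM in ctrl DEC. Star, Inha, Hsd3b1, Cyp17a1, Ptgfr and Akr1c18 are themselves on the ovarian list. These markers were present in each of the 3 libraries, so no count for H2O2 DEC can be given without them.

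**Figure D3:**
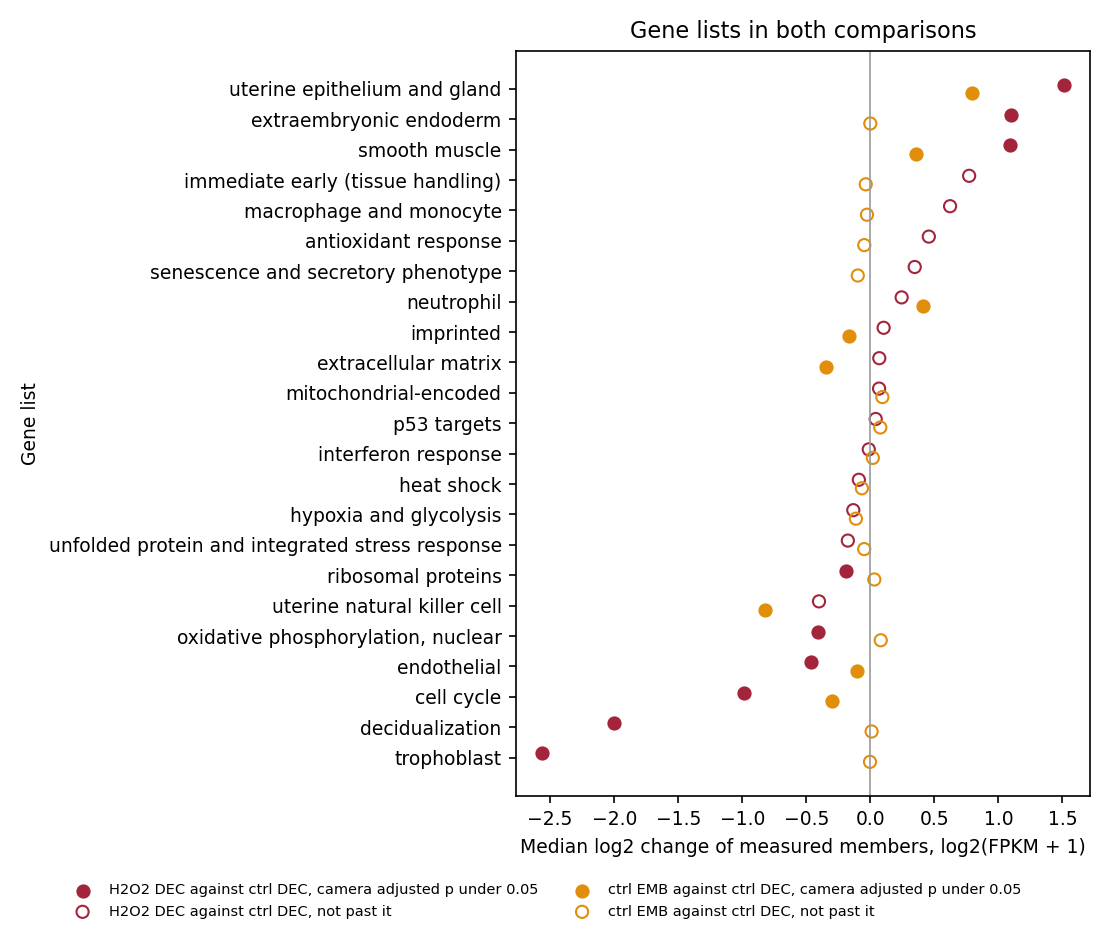
Median log2 change of the measured members of each gene list (vertical axis) in H2O2 DEC and in ctrl EMB, each against ctrl DEC. Filled points passed camera at an adjusted p under 0.05 with the preset correlation, of which 2 of 9 in H2O2 DEC and 6 of 8 in ctrl EMB also passed with an estimated one; the decidualization median is -2.0 in H2O2 DEC and 0.01 in ctrl EMB.

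Several lists had many members that moved without the list passing its test. Of all genes tested 60.2% were called in this comparison, so a list with about that share called does not stand out. This holds here and for the immune, stress and metabolic lists that follow. The antioxidant list had 15 of 28 higher and 8 lower (adjusted p = 0.706). The malic enzyme gene Me1 rose 7.23-fold to 309 ± 13.2 FPKM, the glutathione transferase gene Gsta4 rose to 90.4 ± 4.79 FPKM and Hmox1 (heme oxygenase 1) rose 2.35-fold to 83.6 ± 7.14 FPKM, whereas Gpx3, a secreted glutathione peroxidase and the most abundant nuclear transcript of the ctrl DEC libraries, fell 12-fold to 917 ± 26.3 FPKM. The senescence list had 8 of 16 higher and 5 lower (adjusted p = 0.832, and 6 lower adjusted over the list alone). The cell cycle inhibitor genes Cdkn2b and Cdkn1a rose 51.7-fold and 5.52-fold, to 101 ± 3.70 and 74.7 ± 4.70 FPKM, while Igfbp3 and Serpine1 fell by 3.27 and 2.71 on the log2 scale. The p53 target list had 7 higher and 7 lower of 20 (adjusted p = 0.756, and 8 lower adjusted over the list alone), with the apoptosis gene Pmaip1 falling 34.6-fold and Ddit4l and Btg2 rising by 3.65 and 3.42. The extracellular matrix list had 11 higher and 8 lower of 26 (adjusted p = 0.992). Tnc (tenascin C) rose 128-fold to 133 ± 12.6 FPKM and the protease inhibitor gene Timp1 34.6-fold to 2511 ± 69.8 FPKM, whereas Timp3 fell 11.6-fold.

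Among immune cells, the macrophage list had 10 of 17 higher and 1 lower (adjusted p = 0.0747, and 11 higher adjusted over the list alone), and it was called higher without a filter and with only the 6 samples compared (range over settings 0.0218 to 0.155). Cd14 and Ctss rose 2.69-fold and 2.54-fold, and Csf1r fell 3.12-fold. The uterine natural killer cell list had 2 of 14 higher and 6 lower (adjusted p = 0.115), and was called lower with only the 6 samples compared and with array weights, whose estimation did not converge (range over settings 0.043 to 0.201). The granzyme genes Gzmb and Gzmc, which are close copies of each other and so uncertain, fell by 1.22 and 1.02, Cd7 rose by 2.07, and Prf1 (perforin) went from 9.19 ± 0.514 to 6.65 ± 0.826 FPKM (adjusted p = 0.0132), a call that ended without H2O2 DEC replicate 1 (adjusted p = 0.0517) or 2 (adjusted p = 0.0546; range over alternatives 0.000139 to 0.0546). The neutrophil list had 3 higher and 2 lower of 7 (adjusted p = 0.706); Lcn2 and Ltf, which epithelium also makes, rose 17.8-fold and 6.54-fold and S100a8 fell by 0.75, a call that ended without ctrl DEC replicate 2 (adjusted p = 0.0772) or H2O2 DEC replicate 3 (adjusted p = 0.0757; range over alternatives 0.00129 to 0.0772). The interferon list had 6 higher and 8 lower of 26 (adjusted p = 0.523, and 5 higher adjusted over the list alone), with Irf7 down 16.9-fold, Gbp2 up 6.18-fold and Ifit2 down 4.22-fold.

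Of the stress and metabolic lists, hypoxia and glycolysis had 4 higher and 8 lower of 22 (adjusted p = 0.0826, and 7 lower adjusted over the list alone), with the glucose transporter gene Slc2a1 falling 11.7-fold from 228 ± 11.6 FPKM, P4ha2 by 2.65 and Hk2 by 1.41. The immediate early list, which also responds to tissue handling, had 11 higher and 4 lower of 18 (adjusted p = 0.0725, and 5 lower adjusted over the list alone), with Nr4a1 17.5-fold, Egr2 23.2-fold and Dusp1 8.39-fold higher. It was called higher without a filter, with quantile normalization and with median centring (range over settings 0.0118 to 0.207). The unfolded protein list had 7 higher and 7 lower of 24 (adjusted p = 0.586, and 8 lower adjusted over the list alone), with Atf3, Ddit4 and Trib3 rising by 2.76, 1.91 and 1.86. The heat shock list had 5 higher and 4 lower of 14 (adjusted p = 0.706), with the small heat shock protein gene Cryab falling 22.7-fold and the near-identical, uncertain pair Hspa1b and Hspa1a rising 8.26-fold and 9.14-fold. The imprinted list had 8 higher and 7 lower of 19 (adjusted p = 0.687), with Cdkn1c, Mest and Grb10 falling by 3.13, 2.76 and 2.51. Of 13 mitochondrial-encoded genes 1, mt-Atp6, fell and 0 rose (adjusted p = 0.588), and 0 passed adjusted over the list alone. Lists with under 5 measured members were not tested: of 4 erythroid genes 3 rose (Car2 2.76-fold, Hbb-bs 1.71-fold and Hba-a1 1.59-fold, the globin pair Hba-a1 and Hba-a2 being uncertain copies), of 4 lymphocyte genes 1 rose (the antibody gene Igkc, by 3.44), of 4 epiblast genes 1 rose (Dppa5a, by 3.87) and 1 fell (L1td1, by 1.83), and of 2 totipotency genes Obox5 rose by 3.22 and Arg2 fell by 2.67. Pou5f1, the pluripotency factor, was at 1.11 ± 0.131 FPKM and listed at 0 in each ctrl DEC library. Because these H2O2 DEC libraries also held oocyte transcripts, the rises of Dppa5a, Obox5 and Pou5f1 cannot be assigned to embryonic cells. Median and mean differed in sign for the unfolded protein (-0.18 and 0.17), imprinted (0.10 and -0.21) and epiblast (-0.09 and 0.47) lists, and camera gave a lower direction for p53 targets and mitochondrial-encoded genes, whose medians were 0.04 and 0.07.

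The second comparison asked how the samples labelled as embryonic-like tissue differed from those labelled as decidua, both from control blastoids. Whether both groups came from the same deciduas stays open. The ctrl EMB libraries held decidual genes near the ctrl DEC level and low values of the embryonic genes listed, as given below. The changes therefore cannot be read as those of embryonic cells against decidua. Genes of glandular epithelium were higher in ctrl EMB. Mmp7, an epithelial protease, rose 10.8-fold, from 6.31 ± 0.410 to 68.0 ± 4.37 FPKM (log2 change 3.24, SE 0.10, adjusted p = 7.96e-07), and Wfdc2, a secreted protease inhibitor of uterine glands, 5.02-fold, from 15.1 ± 2.83 to 76.0 ± 24.8 FPKM (adjusted p = 0.0014). Prf1 was lower, at 3.05 ± 0.565 FPKM against 9.19 ± 0.514 FPKM (adjusted p = 0.000441). The decidual gene Prl8a2 stood at 8207 ± 1779.8 FPKM in ctrl EMB and 6129 ± 267 FPKM in ctrl DEC, which did not pass the test (log2 change 0.40, adjusted p = 0.242).

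Other large rises were those of Klk1 (kallikrein 1), from 0.722 ± 0.223 to 12.6 ± 2.61 FPKM, the calcium channel gene Trpv6, from 1.97 ± 0.0795 to 14.7 ± 2.84 FPKM, Pigr, the receptor that carries antibodies across epithelium, from 5.12 ± 0.0998 to 27.9 ± 8.42 FPKM, and the aspartic protease gene Napsa, from 1.40 ± 0.121 to 10.1 ± 2.64 FPKM. The uterine secretory genes Prap1 and Spink1 rose by 2.37 and 2.28 on the log2 scale with wide spread, to 1097 ± 662 and 644 ± 265 FPKM (adjusted p = 0.0153 and adjusted p = 0.00329). The largest falls were those of Rimklb, an amino acid ligase, from 6.49 ± 0.273 to 0.0155 FPKM (log2 change -2.88, SE 0.08, adjusted p = 7.96e-07), and of Erv3, a gene of retroviral origin, from 145 ± 5.4 to 34.2 ± 3.56 FPKM. Rimklb was at 5.70 to 6.84 FPKM in H2O2 DEC, close to ctrl DEC. The matrix gene Mfap4, Igfbp2 and the Wnt antagonist Sfrp1 fell 4.34-fold, 3.22-fold and 3.51-fold. Rpl26, Rpsa-ps10 and Tpi-rs11 fell by 2.03, 1.66 and 1.49, and all are uncertain because they share sequence with other copies. The call of Prap1 ended without ctrl DEC replicate 1, 2 or 3 (adjusted p = 0.0549, 0.058 and 0.0643; range over alternatives 8.7e-06 to 0.0953). The call of Rpl26 ended without any single library other than ctrl EMB replicates 1 and 3 (adjusted p from 0.0583 to 0.129; range 0.00015 to 0.141). On GRCm38, Mmp7 (ENSMUSG00000018623) lies on chromosome 9 from 7692090 to 7699585, Wfdc2 (ENSMUSG00000017723) on chromosome 2 from 164562413 to 164568510, and Rimklb (ENSMUSG00000040649) on chromosome 6 from 122447296 to 122498761, all protein-coding.

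**Figure D4:**
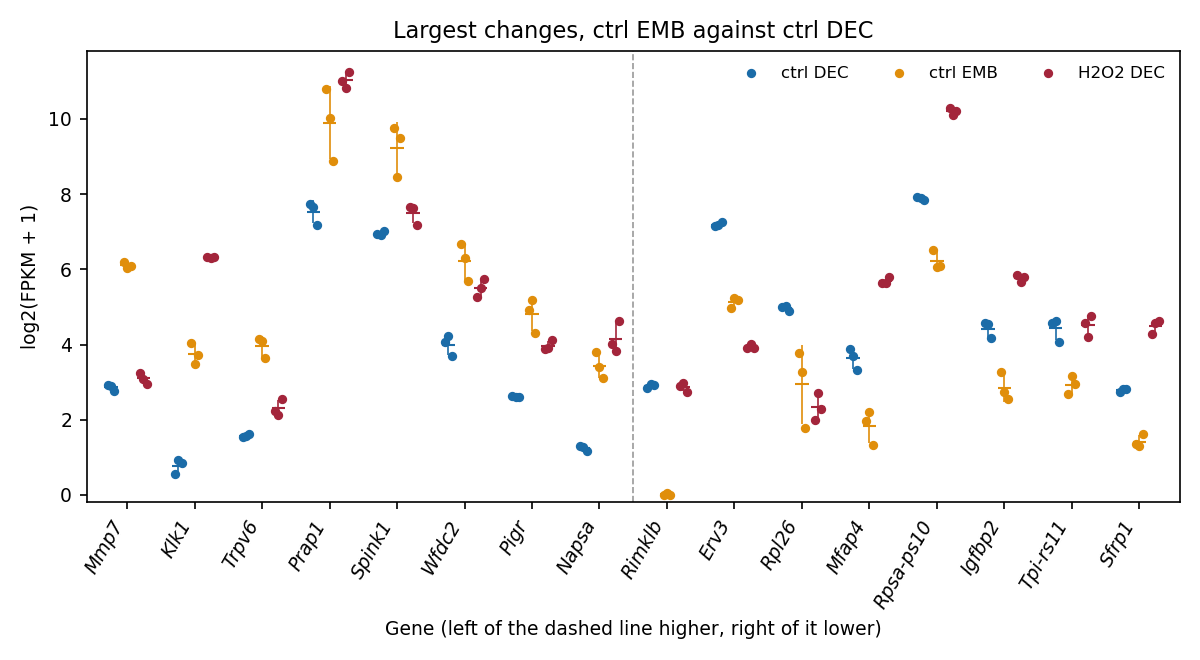
Log2(FPKM + 1) of each library (points) for the 8 genes with the largest rises and the 8 with the largest falls in ctrl EMB against ctrl DEC, with group means (horizontal bars) and SD (vertical bars, n = 3). Mmp7 has a log2 change of 3.24 and Rimklb of -2.88; Prap1, Spink1 and Rpl26 spread most between the ctrl EMB libraries.

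In all, 328 genes were higher and 227 lower in ctrl EMB among the 13386 tested, and 2424 had an unadjusted p under 0.05. More than 2-fold changes numbered 115 higher and 27 lower, 19 of the higher and 19 of the lower genes were predicted genes, and the groups did not overlap for 2909 genes, or 21.7%, where chance gives 10%. Rescaling every library to the same total gave 288 higher and 307 lower, the filter at 5 FPKM 147 higher and 171 lower, the 6 compared libraries alone 156 higher and 55 lower, and array weights, whose estimation did not converge, 2023 and 2470. Single libraries moved these counts by more than 1.5 times: without ctrl DEC replicate 1, 2 or 3 they were 159 and 60, 162 and 59, and 186 and 97, without ctrl EMB replicate 3 they were 550 and 467, and without H2O2 DEC replicate 1, 2 or 3 the lower count was 124, 136 and 145.

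The uterine epithelium and gland list had 10 of 17 members higher, 1 lower and 6 not past the test (median 0.80, adjusted p = 7.62e-15, and adjusted p = 0.0132 with an estimated correlation), or 13 higher adjusted over the list alone. Prss29, an implantation protease of the glands, rose 4.04-fold from 374 ± 54.0 to 1511 ± 501 FPKM, and Cldn7 3.87-fold to 6.62 ± 0.449 FPKM. The smooth muscle list had 5 of 17 higher and 0 lower (median 0.36, adjusted p = 1.19e-05, and adjusted p = 0.0132 with an estimated correlation), or 9 higher and 1 lower adjusted over the list alone, with Myh11 2.23-fold, Lmod1 2.65-fold and Tagln 1.92-fold higher. The neutrophil list had 2 of 7 higher and 0 lower (median 0.41, adjusted p = 0.000299, and adjusted p = 0.0493 with an estimated correlation), or 3 higher adjusted over the list alone. The members that rose were Lcn2 and Ltf, 2.92-fold and 2.51-fold, both of which are also made by uterine epithelium. The call of Tagln ended without ctrl DEC replicate 1, 2 or 3 (adjusted p = 0.0657, 0.074 and 0.0691; range over alternatives 0.00061 to 0.074).

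Matrix and cell cycle genes were lower in ctrl EMB. The extracellular matrix list had 10 of 26 lower and 0 higher (median -0.35, adjusted p = 3.02e-11, and adjusted p = 0.0101 with an estimated correlation), or 16 lower adjusted over the list alone. The collagen genes Col1a1 and Col5a1 fell from 886 ± 20.8 to 563 ± 73.6 FPKM and from 11.9 ± 0.808 to 6.86 ± 0.860 FPKM, and Fn1 (fibronectin) 1.52-fold. The cell cycle list had 7 of 28 lower and 0 higher (median -0.30, adjusted p = 1.97e-10, and adjusted p = 0.00658 with an estimated correlation), or 11 lower adjusted over the list alone, with the kinase gene Aurkb, Cdc20 and Mcm5 falling 1.5-fold, 1.43-fold and 1.40-fold. Mki67 was at 21 ± 3.71 against 26.3 ± 1.90 FPKM (adjusted p = 0.194). The uterine natural killer cell list had 6 of 14 lower and 0 higher (median -0.82, adjusted p = 5.62e-07, but adjusted p = 0.0812 with an estimated correlation), or 10 lower and 1 higher adjusted over the list alone. Beside Prf1, the granzyme genes Gzme and Gzmd, uncertain as close copies, fell 2.22-fold and 2.11-fold. The imprinted list had 1 of 19 lower, H19, which fell from 32.0 ± 1.61 to 22.1 ± 1.76 FPKM, and 0 higher (median -0.17, adjusted p = 0.00196, and adjusted p = 0.0448 with an estimated correlation), or 6 lower adjusted over the list alone. The endothelial list had 2 of 21 lower and 0 higher (median -0.10, adjusted p = 0.0155, but adjusted p = 0.216 with an estimated correlation, and 0.192 without ctrl EMB replicate 3, in a range over alternatives of 0.000558 to 0.216; the call also ended with the filter at 5 FPKM and with array weights), namely Eng and Plvap, which fell 1.46-fold and 1.40-fold. Several of these gene calls ended when 1 library was left out. Without ctrl DEC replicate 1 or 2 this held for Aurkb (adjusted p = 0.0647 and 0.0514), Mcm5 (0.0842 and 0.0724), Gzmd (0.0793 and 0.0716), and Gzme (0.102 and 0.108, and 0.0508 without H2O2 DEC replicate 1), and without ctrl DEC replicate 1, 2 or 3 for Col1a1 (0.0831, 0.0758 and 0.0549) and H19 (0.0704, 0.067 and 0.071). The call of Plvap ended without ctrl DEC replicate 1 or 2, ctrl EMB replicate 2 or H2O2 DEC replicate 1 or 2 (0.0543 to 0.135). The call of Cdc20 ended without any single library other than ctrl EMB replicates 1 and 3 (0.0544 to 0.124). Over all alternatives the adjusted p of these 8 genes ran from 1.61e-05 to 0.135.

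The decidualization, trophoblast and extraembryonic endoderm lists did not pass their tests in ctrl EMB. The decidualization list had 1 of 30 higher and 2 lower (median 0.01, adjusted p = 0.864), or 3 lower adjusted over the list alone: Prl3c1 rose from 798 ± 59.6 to 1279 ± 239 FPKM, and Htra1 and Bmp8a fell 1.95-fold and 1.51-fold. The call of Prl3c1 ended without ctrl DEC replicate 1, 2 or 3 (adjusted p = 0.111, 0.112 and 0.052) or H2O2 DEC replicate 1, 2 or 3 (0.0568, 0.0544 and 0.0509; range over alternatives 9.47e-05 to 0.289). The call of Bmp8a ended without ctrl DEC replicate 1, 2 or 3 (0.0582, 0.074 and 0.052; range 0.000499 to 0.215). Bmp2 was at 374 ± 23.8 against 335 ± 10.7 FPKM and Hand2 at 442 ± 59.2 against 508 ± 52.0 FPKM, neither past the test, although both passed with array weights, whose estimation did not converge (adjusted p = 0.0147 and 0.008; ranges over alternatives 0.0147 to 0.762 and 0.008 to 0.754). The trophoblast list had 0 of 5 members past the test (adjusted p = 0.744). Of its 24 listed genes 6 were at 1 FPKM or more in ctrl EMB, the highest being Gjb3, at 27.9 ± 9.14 against 27.1 ± 4.41 FPKM in ctrl DEC. Plac1 was at 1.04 ± 0.0143 FPKM against 0.624 ± 0.166 FPKM, and Tpbpa was at 1.04 ± 0.134 FPKM against 0.577 ± 0.0799 FPKM, both below the filter. Pou5f1 and Prl3d1 were listed at 0 in each ctrl EMB library and Afp was at 0.0052 FPKM. The extraembryonic endoderm list had 3 of 13 higher and 1 lower (adjusted p = 0.417, and 2 lower adjusted over the list alone), with Spink1, Hnf1b and Trf rising, Hnf1b 4.68-fold to 4.07 ± 0.933 FPKM, and Lama1 falling 1.59-fold, a call that ended without ctrl DEC replicate 1 (adjusted p = 0.0876) or 2 (adjusted p = 0.0917; range over alternatives 0.000127 to 0.0941). Spink1 and Hnf1b are also genes of uterine glands. None of the 4 measured epiblast genes and none of the 2 measured totipotency genes passed the test, and of 4 erythroid and 4 lymphocyte genes Car2 and Igkc rose, by 0.69 and 1.61.

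The p53 target list had 3 of 20 higher and 0 lower (adjusted p = 0.141, and 4 higher adjusted over the list alone), with Btg2, Ddit4l and Pmaip1 rising by 0.55, 0.50 and 0.37. The list was called higher with the filter at 5 FPKM (adjusted p = 0.0152; range over settings and left-out libraries 0.0152 to 0.239). The call of Btg2 ended without any single library other than ctrl EMB replicates 1 and 3 and H2O2 DEC replicate 3 (adjusted p from 0.0505 to 0.1), that of Ddit4l without any other than ctrl EMB replicates 1 and 3 (0.0824 to 0.191). The call of Pmaip1 ended without any library other than ctrl EMB replicate 3 (0.0512 to 0.178). Over all alternatives the adjusted p of these 3 genes ran from 0.000267 to 0.191. Cdkn1a was at 17.6 ± 1.82 against 13.5 ± 0.523 FPKM (adjusted p = 0.0813, and 0.0216 without ctrl EMB replicate 3, a call also gained with array weights and with length and GC trends removed, in a range over alternatives of 0.00085 to 0.273) and Hmox1 at 30.1 ± 7.44 against 35.5 ± 3.21 FPKM (adjusted p = 0.502). The antioxidant, interferon, heat shock, immediate early and mitochondrial-encoded lists had 0 members past the test over all genes. Adjusted over the list alone, the immediate early list had 1 higher and 2 lower, and the senescence list, with 1 lower over all genes, had 1 higher and 3 lower. In the other lists, the members past it were Cd14 (higher), and Igfbp5, Pgam1, Eno1, Psat1, Phgdh and Uqcrc1 (lower), and 2 of 79 ribosomal protein genes (lower). Without ctrl EMB replicate 1 the oxidative phosphorylation and ribosomal protein lists were called lower (adjusted p = 0.0315 and 0.0143) and the mitochondrial-encoded list higher (0.0215). Without ctrl EMB replicate 3 the ribosomal protein list was called higher (0.000684). Over alternatives the adjusted p of these 3 lists ran from 0.000684 to 0.994. Median and mean differed in sign for the decidualization (0.01 and -0.02), trophoblast (0.00 and 0.03), extraembryonic endoderm and erythroid (-0.10 and 0.01) lists, and camera gave a higher direction for macrophages and a lower one for oxidative phosphorylation against the sign of their medians (-0.03 and 0.08).

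The comparisons share the ctrl DEC libraries, which alone makes their changes move together. The covariance of the log2 changes across genes was 0.0522, against 0.0145 in 100 simulated pairs of unchanged groups with the same controls (highest 0.0159), an excess of 0.0377. Pearson's r was 0.155, against 0.502 in the simulated pairs. Genes higher in both comparisons numbered 240, where independent lists of these sizes would share 121, and genes lower in both 106, against 53. Genes higher in H2O2 DEC and lower in ctrl EMB numbered 69, against 83.7, and the reverse 39, against 76.5. The simulated pairs shared 0 calls. Unchanged groups give almost no calls to share, so this count does not measure how much overlap the shared controls add. The uterine epithelium and gland and smooth muscle lists were called higher and the cell cycle and endothelial lists lower in both comparisons with the preset correlation. With an estimated correlation only the cell cycle list was called in both, since the other 3 lost the H2O2 DEC call and the endothelial list the ctrl EMB call too. Cldn7 and Myh11 rose and Plvap fell in each comparison, the call of Plvap in ctrl EMB being one that single libraries ended. The ctrl DEC group is too small to be split, so part of the overlap above that of independent lists may come from the shared controls.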

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

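Voom on the implied fragments and removal of each library's length and GC trend were chosen after the data had been seen. In H2O2 DEC against ctrl DEC the number of genes higher, 4933, fell to 2598 with the filter at a mean of 5 FPKM, where fewer genes were tested. The lower count stayed within 1.5 times of 3124 under every alternative, and leaving out each library in turn gave 4347 to 5458 higher and 2671 to 3577 lower. In ctrl EMB against ctrl DEC, where the main counts were 328 and 227, the filter at 5 FPKM gave 147 higher and the 6 compared libraries alone gave 156 higher and 55 lower. The latter setting raised the H2O2 DEC counts, to 5638 higher and 3762 lower. The root mean square SD of the log2 values was 0.323 in ctrl EMB, 0.169 in ctrl DEC and 0.171 in H2O2 DEC. The main fit shares 1 estimate of the spread per gene over these groups, which is on average below that of ctrl EMB, so the main ctrl EMB counts may be too high. Array weights, whose estimation stopped before it converged, gave 2023 and 2470. Removing the length and GC trends gave 474 higher and 467 lower, and leaving out each library in turn gave 159 to 550 higher and 59 to 467 lower; the cause was not tested. Voom gave 4978 higher and 3099 lower in H2O2 DEC and 327 and 253 in ctrl EMB. The 3 higher and 6 lower lists of H2O2 DEC became 0 and 2 with an estimated correlation, and 10 higher and 8 lower with fry, which tests a list by itself. The 3 higher and 5 lower lists of ctrl EMB became 3 higher and 3 lower with an estimated correlation, and 5 higher and 7 lower with fry. The covariance of the comparisons rose from 0.0522 to 0.109 with a pseudocount of 0.1, which widens the changes of low genes, and that of the simulated pairs from 0.0145 to 0.0308. With the filter at 5 FPKM the genes higher in both numbered 105, where independent lists would share 47.5, and those lower in H2O2 DEC and higher in ctrl EMB 25, against 40.3. With the replicate number as a block, H2O2 DEC had 4831 higher and 3042 lower genes and ctrl EMB 221 and 89. The numbers did not pair H2O2 DEC with the other groups: deviations of libraries with the same number correlated at -0.29 to -0.06 with ctrl DEC and -0.38 to -0.10 with ctrl EMB. Between ctrl DEC and ctrl EMB they correlated at 0.37, 0.04 and 0.48 for replicates 1, 2 and 3. Of 18 combinations of a library with another group, the library correlated best with its own number in 5, all between ctrl DEC and ctrl EMB. Whether ctrl DEC and ctrl EMB were paired by number therefore stays open. No gene called in the main analysis was called in the opposite direction under any alternative. For the named genes, 2118 values under alternatives in H2O2 DEC kept direction and side of the threshold and 10 lost the call (6 of them for Atp5o, whose adjusted p reached 0.1); in ctrl EMB 1047 kept it, 120 lost it and 5 gained it. Depth limits the genes below about 0.2 FPKM.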

Other observations

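The ovarian, uterine position and Y-linked tests were set after the fixed lists had been seen and before their own values were. The test of embryonic RNA in ctrl EMB, for which the values of 1 of its lists were already known, the test of dilution and the tests of spread after removal of length or GC trends were chosen only after the result was seen.

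Of 21 ovarian somatic markers, 20 had their lowest H2O2 DEC value above all 6 other libraries, with a median of 105 FPKM in H2O2 DEC and 1.10 FPKM in ctrl DEC. The granulosa cell hormone gene Amh stood at 79.6 ± 5.02 against 0.17 FPKM, the gonadotropin receptor gene Lhcgr at 35.4 ± 0.944 against 0.00495 FPKM, and Fshr and Nr5a1 at 15.6 ± 0.577 and 55.9 ± 4.68 FPKM and listed at 0 in each ctrl DEC library. Insl3 was the tested exception, at 1.87 ± 0.808 against 1.97 ± 0.587 FPKM. Of the 21, 11 were above 1 FPKM in ctrl DEC too. Of 20 oocyte markers, 19 were listed and all of these lay above the 6 other libraries, with a median of 10.1 FPKM in H2O2 DEC and 0 of them above 1 FPKM in ctrl DEC. The most abundant were Nlrp14, Zp3, Gdf9 and Padi6, at 34.6, 34.4, 34.2 and 32.1 FPKM.

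Of 10 ciliated cell markers of the oviduct, 8 had their lowest H2O2 DEC value above all 6 other libraries, with a median of 0.803 FPKM in H2O2 DEC and 0.0493 FPKM in ctrl DEC. Foxj1 stood at 0.800 ± 0.227 against 0.0288 FPKM, Dynlrb2 at 1.70 ± 0.659 FPKM and listed at 0 in each ctrl DEC library, and 2 of 2 tested were higher. Of 5 tested adipose genes 3 were higher and 2 lower, with Fabp4 at 2.87 against 62.4 FPKM and Adipoq at 4.05 against 0.0138 FPKM. The kidney gene Kap was the 1 tested of its list and higher, at 7.18 FPKM; of the adrenal list the 1 tested, Cyp11b1, was lower; of 3 tested skeletal muscle genes 1, Tnnt3, was higher; no liver gene reached the filter, with a median of 0.226 FPKM. Of 8 tested uterine position genes 7 fell and 1 rose: Hoxd10 went from 87.4 to 9.98 FPKM and Hoxa9 from 21.5 to 0.874 FPKM, whereas Hoxc8 went from 0.02 to 4.97 FPKM. Of 3 tested genes of post-implantation mesoderm and neural tissue 2 fell in H2O2 DEC, and 0 of 6 placental lactogen and embryonic growth genes reached the filter.

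The H2O2 DEC libraries stood apart from ctrl DEC by 8057 genes. Simple dilution of a ctrl-like decidua by other RNA would lower its genes by about 1 common factor, and the interquartile range of the log2 ratios over the 30 decidualization genes was 3.50 (quartiles -4.01 and -0.51). This range does not decide it, because 5 of the 30 were called higher, Cyp11a1 among them. Other RNA that carries such genes would widen the range by itself. Such RNA can only raise a gene above the level that a share of ctrl-like decidua gives, so the low ratios limit that share. The lower quartile of -4.01 and the lowest log2 ratio of -11.76 argue against a large share of ctrl-like decidua, for these genes. Dilution to a small share, or replacement by another tissue, stays open. Ovarian and oocyte transcripts were present in all 3 libraries of the group. A candidate explanation is that ovarian tissue was part of the H2O2 DEC samples: the smaller of the median log2 differences of the ovarian and oocyte lists was 3.35, and the labels describe no step that would remove such tissue. Whether these were decidua with ovary attached, or ovary or other tissue under a decidua label, was not tested and stays open, so the H2O2 DEC values are those of decidua only as far as the labels hold. Whether the uterine part of these samples lacked a decidual response stays open. The median of the uterine position genes was -0.60 over the 11 listed (quartiles -2.54 and 0.35) and -1.71 over the 8 tested (quartiles -2.99 and -0.53). The fall of 2-fold set as the limit lies within both ranges. Of the 11, Hoxc9 and Hoxc10 were near the floor in ctrl DEC, and Wnt7a was low there, at 0.215 FPKM. Of the 8, 7 fell, and Hoxc8, which rose, was near the floor in ctrl DEC. The 7 were those above 1 FPKM in ctrl DEC. Hoxa9, Hoxd10, Hoxd11 and Emx2 fell by 3.59, 3.01, 2.98 and 2.10, and Hoxd9, Wnt5a and Hoxd8 by 1.32, 0.60 and 0.32. Hoxa10 and Hoxa11, which are on the decidualization list and not on this one, each fell by more than Hoxa9. An effect of H2O2 on the blastoids, which the design names, was not tested apart from the explanations above, since all 3 libraries of the group carried the ovarian markers.

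The ctrl EMB libraries resembled ctrl DEC, with 555 genes called. A candidate explanation is that they held mostly decidual RNA with few embryonic cells: the larger of the median levels of the embryo lists in ctrl EMB was 0.159 FPKM, and for those same genes it was 0.294 FPKM in ctrl DEC. Above 1 FPKM in ctrl EMB were 3 of the 13 listed mesoderm and neural genes, and 3 in ctrl DEC too. Placental genes that went the other way were Plac1, at 1.04 ± 0.0143 against 0.624 ± 0.166 FPKM without overlap, and Tpbpa, at 1.04 ± 0.134 against 0.577 ± 0.0799 FPKM, so a small share of trophoblast is not excluded. Rimklb, present in ctrl DEC and H2O2 DEC, was near the floor in ctrl EMB, which mostly decidual RNA like that of ctrl DEC would not give. It was taken from the largest falls, so it does not decide the question for the libraries as a whole. Male embryonic cells could not be judged from the Y-linked genes, because only Eif2s3y of 4 was listed, at 0 in ctrl EMB, and the sex of the transferred cells is not given in the sources used here. The decidualization list, fixed before the data were examined, had a median log2 change of 0.01 in ctrl EMB against ctrl DEC. Of its 30 genes 27 did not pass the test, 1 was higher and 2 were lower. These values argue against a tissue with little decidual RNA, for the genes of that list. An embryonic-like part in which the embryonic genes of these lists are low, which the design would allow, was not tested.

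The ctrl EMB replicates spread more than the ctrl DEC replicates, with a root mean square SD of the log2 values of 0.323 against 0.169. Trends with transcript length and GC content were present between ctrl EMB replicates 1 and 3 (Spearman's rho across 13316 genes of -0.31 and 0.51, which met the bound of 0.3 first set for them), and also between ctrl DEC replicates 1 and 3 (-0.25 and 0.53). Removing the length trend left 0.312 and removing the GC trend 0.298 in ctrl EMB, against 0.166 and 0.157 in ctrl DEC, which argues against either trend as the whole cause. With both removed the ctrl EMB spread was 0.292, and differences in the tissue taken for each replicate were not tested.

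The libraries of each comparison can be divided in 10 ways into 3 and 3, too few for a share under 0.05. Every split other than the real one mixes libraries of both groups, so the group difference enters the spread and keeps genes from being called. A gene count of 0 in those splits is therefore no support for the real one. For H2O2 DEC against ctrl DEC, 1 of the 10 splits, the real one, gave 8057 genes and the highest other gave 0, while 2 of 10 gave at least the real 9 gene lists, the highest other giving 10. For ctrl EMB against ctrl DEC, 1 of 10 gave 555 genes and the highest other 0, and 1 of 10 gave 8 lists and the highest other 7.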
